A study of Homo sapiens with 4 samples.

How the data were processed

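The data are RNA sequencing of 4 samples of established human hepatocellular carcinoma lines, Huh7 and Hep3B, under normoxia or hypoxia, with 1 library per line and condition. Per the labels, every sample was treated with MNNG, and no sample without MNNG was analysed here. Sample titles name the line and either a control or 48 h, and the treatment label was used for the oxygen condition. The dose and the time are those of the series design, and the titles do not show that the controls had the same treatment time. Per the labels' protocols, RNA was extracted with a column kit and libraries were made from 1.3 µg of total RNA with a SMARTer mRNA kit. The genome build was GRCh38.p14 per the submitters' processing notes, and the aligner and counter are not given in the sources used here.

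Each line had 1 table. Per the file headers the authors gave, for each gene and library, an estimated read count, FPKM and TPM, together with a log2 ratio, a p-value and an FDR. The deposited estimated counts (expected counts) were not whole for 14.2% to 16.5% of values, depending on the library, which is how reads shared between genes appear. In the deposited tables the authors' log2 ratio equalled the ratio of hypoxia to normoxia FPKM with zeros set to 0.01, for all 2170 and 2682 genes. The deposited FPKM and TPM values differ by a fixed factor per library, from the values. The deposited p-value columns come from a test whose name is not given in the sources used here, and the largest FDR was 0.000979 in Huh7 and 0.000994 in Hep3B. All genes in the authors' deposited tables were mRNA with an absolute log2 ratio of at least 1, so the tables had been filtered at a log2 ratio of 1 and an FDR of 0.001. In the authors' deposited tables the share of genes higher was 34.6% for Huh7 and 62.3% for Hep3B.

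Because the tables hold part of each library, library totals were recovered from the reads and FPKM. The normoxia total was the median implied by single-transcript genes of at least 2000 bases and 100 reads (47 genes for Huh7, quartiles 14.9 and 16.5 M reads; 60 for Hep3B, quartiles 14.1 and 15.5 M reads), and the ratio of the totals within a line was taken from 300 and 346 genes of at least 500 reads and an FPKM of 5 (0.960 and 1.05). Ratios within a line depend on that ratio, and levels in CPM on the totals. Estimated counts were divided by these totals to give CPM, and log2 ratios used a prior count of 2 scaled to the library as edgeR does. Folds are ratios of CPM without the prior count, so they exceed the log2 ratio given beside them where reads are few. TMM had been chosen as the scaling before the data were examined, together with the groups, tests, gene lists and alternatives. It assumes that most genes do not differ, which a table of differing genes breaks, so library totals, which had also been set down beforehand as another scaling to try, were used for all values given. Relative to it TMM moved the log2 ratios by 0.909 in Huh7 and -0.661 in Hep3B, median-ratio factors by 1.13 and -1.17, and TPM by -0.236 and -0.0267 against FPKM. Implied transcript length is reads divided by FPKM and the total, so it is the length the authors' counting used. Coordinates are those of the tables.

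Genes of at least 1 CPM in a library of the line were counted (2152 and 2653). Counting intervals are exact 95% binomial (Clopper-Pearson) intervals of the split of a gene's reads between the 2 libraries. They and the floors cover counting error only, since reads were not collapsed to molecules. A fold against 0 reads was computed against 3 reads and is a lower bound. Genes with fractional reads (417, or 19.2%, in Huh7 and 498, or 18.6%, in Hep3B; tolerance 0.005 reads) share reads with other genes and are reported as uncertain.

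Over both lines the estimated counts of the 784 genes in both tables were rounded to whole numbers and tested with edgeR's quasi-likelihood test with the line as a block, 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. The lines, which pair the libraries, were the only replicates. On simulated data for this comparison (781 genes) the test called 85 of 100 genes changed 2-fold, 100 of 100 changed 4-fold and 3 of 581 unchanged. The simulation gave both lines the same change, left most genes unchanged and used a far smaller dispersion than the 0.285 fitted to the real counts. It therefore does not show how many changed genes the test would call in these libraries. DESeq2 and limma on log2(FPKM + 1) were alternatives, as were other scalings, prior counts, filters and fold thresholds. On the log2(FPKM + 1) scale low genes show smaller changes.

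The 34 gene lists had been fixed with the design. For a list with at least 3 listed members in a line, its median log2 ratio was placed among 10000 random lists of the same size drawn from the listed genes of that line and matched on mean expression in 20 bins. Percentiles describe these libraries and are not tests. Lists overlap: GDF15, HMOX1, SLC2A1, LDHA, BNIP3, BNIP3L and DDIT4 are among genes in more than 1. Genes are named by a rule fixed with the design: the 12 highest and 12 lowest shared ratios by the smaller of the lines' absolute values, the 6 highest and 6 lowest of each line and the 5 largest opposite ratios of each kind, all with a mean of at least 5 CPM, up to 4 listed members per list, and 13 genes named outright. CDT1 falls outside it and was named because it was the only listed member of its list. Some genes chosen by this rule, and 1 of the lists, are not reported here.

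Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Gene identifiers of 2162 Huh7 and 2670 Hep3B genes were found in the RefSeq gene table, and GC shares were known for 98.6% of genes of both tables.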

Results

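RNA was sequenced from Huh7 and Hep3B, a pair of human hepatocellular carcinoma cell lines, under normoxia or hypoxia, for 48 h per the series design. Per the treatment labels all 4 samples had received MNNG (50 µM per the design), a DNA-alkylating agent that drives PARP1 into overactivity and is widely used to trigger parthanatos, a form of cell death that depends on PARP1. The series concerns how hypoxia acts on parthanatos, and each comparison asks how gene expression in MNNG-treated cells differed between hypoxia and normoxia. The titles mark the normoxia samples only as controls and give 48 h for the hypoxia samples alone, so the treatment and time of the controls, on which every ratio depends, rest on the labels and the design. Each line and condition had 1 library. The tables analysed here hold only genes that passed the authors' own thresholds, 2170 for Huh7 and 2682 for Hep3B, of which 784 stood in both. Recovered library totals were 15.9 M reads (Huh7 normoxia), 15.3 M (Huh7 hypoxia), 14.7 M (Hep3B normoxia) and 15.5 M (Hep3B hypoxia), and the listed genes held 14.5%, 14.7%, 19.3% and 20% of them. With 1 library per condition no difference within a line has a replicate check. Ratios within a line therefore have 95% counting intervals, printed for part of the genes, in place of a replicate error, and no p-value. A gene with no entry in a table analysed here is not thereby shown to be unchanged.

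In Huh7 cells hypoxia went with higher transcripts of oxygen-regulated, glycolytic and oxidative-stress genes and with lower transcripts of lipid-synthesis and hepatocyte genes. PPFIA4, a liprin family gene induced by hypoxia-inducible factor (HIF), went from 1.07 to 23.5 CPM (counts scaled to the library total), a 22.0-fold difference of the plain CPM values (log2 ratio with a prior count of 2, 4.30, counting interval 3.76 to 5.25). HMOX1, which encodes the heme-degrading enzyme heme oxygenase, was 11.5-fold higher (log2 3.52, interval 3.41 to 3.65). At the other end GPAM, whose product catalyses the initial step of glycerolipid synthesis, was 16.3-fold lower (log2 -3.97, interval -4.48 to -3.60). PARP1 was 2.47-fold lower, from 418 to 170 CPM, a difference that depends on the scaling. Among the 2152 listed genes of at least 1 CPM, 690 were at least 2-fold higher under hypoxia and 1339 at least 2-fold lower, so 34.0% of these were higher.

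All 24 listed members of the 39 HIF targets were higher in the Huh7 hypoxia library, with a median log2 ratio of 1.71, above every one of 10000 random lists of listed genes matched on expression (percentile 100). ANGPTL4, a secreted inhibitor of lipoprotein lipase, had a log2 ratio of 3.84, and PFKFB4, which makes a glycolytic activator, 3.30. CA9, the HIF-induced carbonic anhydrase, went from 2 reads to 21 (log2 2.56, counting interval 1.42 to 6.59), and EPO, which encodes erythropoietin, had a log2 ratio of 0.99. Of 19 glycolysis genes 16 were listed and all 16 were higher (median 1.64, percentile 99.96), among them ENO2 (3.57), ALDOC (3.03) and PFKP (2.05, 4 reads to 22, counting interval 0.96 to 4.51). SLC2A3, a glucose transporter gene, stood at 3.84, but part of its reads were shared with other genes. All 4 listed members of the mitophagy and autophagy list were higher as well (median 1.48, percentile 95.2), including the mitophagy receptor genes BNIP3 (1.86, shared reads) and BNIP3L (1.64). Of the regulators of the HIF pathway only EP300, a transcriptional coactivator gene, was listed for Huh7, at -1.36, and HIF1A and EPAS1 had no entry for either line.

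Stress-response lists were mostly higher in hypoxic Huh7 cells. Each of the 10 listed NRF2 targets was higher (median 1.81, percentile 99.99), led by AKR1B10 at 4.11, with shared reads, and HMOX1 at 3.52. In the integrated stress response list 7 listed members were higher and 1 lower (median 1.62, percentile 99.7), with GDF15, a stress-induced cytokine gene, at 3.23, DDIT4, an mTOR inhibitor gene, at 2.13 and SLC3A2, an amino acid transporter subunit gene, at 1.70. All 10 listed early response genes were higher (median 1.51, percentile 99.9), FOSB with a log2 ratio of 3.34 and KLF4 with 1.99. The extracellular matrix and EMT list had 7 members higher and 1 lower (median 1.49, percentile 99.6), with the collagen cross-linking enzyme gene LOXL2 at 2.30. Of 3 listed heat shock genes HMOX1 and CRYAB (2.30) were higher (median 2.30, percentile 99.5), and the other was lower but turned higher under median-ratio scaling. Among 3 listed histone genes H2AC8 (1.28) and H2BC5 (1.25) were higher and H2AC6 (-1.25) lower (percentile 86.6). The 3 listed ER chaperone genes were lower, with PDIA4 at -1.34 and HYOU1 at -1.24, while 1 of the 3 turned higher under median-ratio scaling.

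Of the 15 genes for parthanatos and poly(ADP-ribose) turnover 3 were listed for Huh7. PARP1 (NCBI gene 142, chromosome 1 from 226360691 to 226408093, GRCh38.p14), which encodes the poly(ADP-ribose) polymerase that starts parthanatos, had a log2 ratio of -1.30 (interval -1.37 to -1.24). PARG (NCBI gene 8505, chromosome 10 from 49818274 to 49942027), which encodes the enzyme that degrades the polymer, had -1.33 (interval -1.61 to -1.08). The authors' log2 ratio of FPKM for PARG was smaller, at -1.04, outside that interval. MIF (NCBI gene 4282, chromosome 22 from 23894383 to 23895223), whose product acts as the nuclease of parthanatos, was 3.25-fold higher, at 1.70 (interval 1.64 to 1.76). AIFM1, which encodes the apoptosis-inducing factor, had no entry in either table, nor had MGMT, the alkylguanine repair gene. The median of the 3 was -1.30, at percentile 17.1. Under TMM scaling, which adds 0.909 to each Huh7 log2 ratio, and median-ratio scaling, which adds 1.13, the log2 ratio of PARP1 shrank to -0.39 and -0.18 and that of PARG to -0.43 and -0.21, while that of MIF was 2.61 and 2.82.

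Listed members of the lists for alkylation and base excision repair, homologous recombination and S phase were lower in Huh7, where 66.0% of the 2-fold genes were lower. In the alkylation and base excision repair list MSH6 (-1.24), UNG (-1.15) and LIG3 (-0.86, shared reads) were among the 4 listed members, all lower (median -1.09, percentile 38.5), but LIG3 turned higher under TMM, and 2 of the 4 and the median itself under median-ratio scaling. PALB2 (-1.11) and RAD51AP1 (-1.03) were the 2 listed members of the homologous recombination list, and both turned higher under that scaling. All 7 listed S phase genes were lower (median -1.36, percentile 5.60), led by the ribonucleotide reductase gene RRM1 (-1.83) and the replicative helicase gene MCM6 (-1.71), with 2 of the 7 turned by median-ratio scaling. TOP2A (-1.22) was the only listed G2 and M phase gene. In the apoptosis list 4 members were listed and all were higher (median 0.97, percentile 87.6), among them BIK (1.97), BMF (0.98) and BBC3 (0.95). The ferroptosis list had 3 members higher and ACSL4 lower at -1.73 (median 2.09, percentile 99.7). The higher ones were ALOX12 (2.48) and HMOX1 and SLC3A2, which other lists also hold. Over resampled members the median ran from -1.73 to 3.52. No member of the necroptosis and pyroptosis list was listed for Huh7.

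Lipid and hepatocyte genes were lower in the same library. All 7 listed genes of fatty acid synthesis and storage were lower (median -1.55, percentile 1.02), with ELOVL6 at -1.68 (shared reads) and FABP1 at -1.38 beside GPAM, and 1 of the 7 turned under median-ratio scaling. Cholesterol synthesis had 9 listed members, all lower (median -1.35, percentile 1.91), with HMGCS1 at -1.81 and SQLE at -1.40, and with 2 of the 9 turned by the same scaling. The 4 listed fatty acid oxidation genes were lower (median -1.70, percentile 1.6), with HADH at -1.74, and 1 of the 4 turned. Among hepatocyte secreted proteins all 8 listed genes were lower (median -1.35, percentile 6.70), and 2 of the 8 turned; ALB, which encodes albumin, went from 7791 to 2882 CPM. The hepatocyte metabolism list had 4 members lower and 1 higher (median -1.69, percentile 1.76), with CPS1 at -1.66. Oncofetal liver markers had 3 lower, including SALL4 at -1.81, and 1 higher (median -1.24, percentile 19). NAD metabolism had 4 higher and 3 lower, the lower ones TDO2 (-2.17), NNT (-1.33, shared reads) and NADK2 (-1.07), of which NADK2 turned higher under median-ratio scaling.

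Immune-type lists were mixed in Huh7. In the inflammatory chemokine and NF-kB list LCN2 (-2.04) and CXCL2 (-1.0) were among 4 lower members against 3 higher (median -1.0, percentile 76.2), with 5 higher and a median of 0.11 under median-ratio scaling. Interferon-stimulated genes had ISG15 at 1.57 among 2 higher and IFIH1 at -2.05 among 3 lower (median -1.03, percentile 58.9), with 3 higher and a median of 0.07 under that scaling. Markers of other cell types were also listed, CD3D at 1.98 (34 to 135 reads), CD68 at 1.28 and the collagen gene COL1A1 at 2.52. NDUFV1 (-1.11) was the only one of 46 nuclear respiratory chain genes listed and turned to 0.01 under median-ratio scaling. None of the 13 mitochondrially encoded genes or the 30 ribosomal protein genes was listed for either line.

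Transcript length moved with direction in Huh7. Listed genes higher under hypoxia had a median implied transcript length of 1901 bases and those lower 4325 bases, and the share of genes higher fell from 76.3% in the shortest of 5 equal groups to 7.83% in the longest. In Hep3B the shares were 63.3% and 58.8%. Median lengths of lists that were lower in Huh7 were 6737 bases for fatty acid synthesis and storage, 4322 for cholesterol synthesis, 2988 for fatty acid oxidation, 2593 for hepatocyte metabolism and 2585 for hepatocyte secreted proteins, and of higher lists 3001 for HIF targets and 2086 for glycolysis. PARP1 (4044 bases) and PARG (3768 bases), both lower, and MIF (318 bases), higher, followed the length trend. Random lists were also matched on length together with expression, the latter in coarser bins than before, so a changed percentile need not come from length alone. Among these, fatty acid synthesis stood at percentile 1.12, cholesterol synthesis at 6.38, S phase genes at 7.06, hepatocyte secreted proteins at 1.88, glycolysis at 99.9 and HIF targets at 100.

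**Figure D1:**
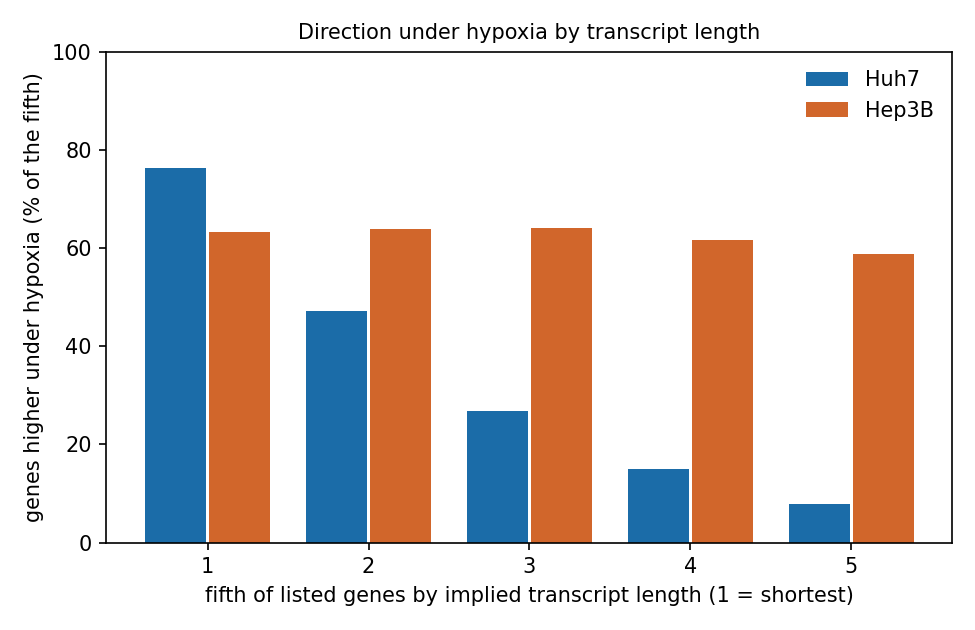
Share of listed genes higher under hypoxia (vertical axis, percent) in 5 equal groups of genes by implied transcript length (horizontal axis, 1 the shortest), for Huh7 (blue) and Hep3B (orange), from 1 library per condition. In Huh7 the share went from 76.3% to 7.83%, and in Hep3B from 63.3% to 58.8%.

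The genes with the highest and lowest ratios in Huh7 included several whose reads were shared with an overlapping or near-identical gene. CXCR5 (log2 5.06), the read-through gene ARPIN-AP3S2 (at least 116-fold lower), UTP14C (at least 103-fold lower), ABCF2-H2BE1 (-5.33), SFT2D3 (-3.88) and BMI1 (-3.53) are therefore uncertain. LDHB, a lactate dehydrogenase gene, was at 4.14 (8 to 168 reads) and NPPB, which encodes brain natriuretic peptide, at 3.96. The split of genes at least 2-fold higher or lower in Huh7 depends on the scaling. With recovered library totals 34.0% were higher, with TMM 78.3% (739 higher, 205 lower) and with median-ratio factors 83.9% (739 higher, 142 lower). Both factors were computed over genes that had been chosen for differing. They moved lower genes below 2-fold, while genes that they would lift past 2-fold were not listed. The shares are therefore not comparable between scalings. Under TMM only LIG3 among the list members changed direction in Huh7.

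In Hep3B cells HIF targets, glycolysis genes and stress-response genes were higher under hypoxia, and lipid-synthesis and hepatocyte genes lower. ANGPTL4 went from 3 reads to 935 (log2 7.49, counting interval 6.66 to 10.49) and CA9 from 18.7 to 749 CPM, 40.1-fold higher (log2 5.32, interval 5.15 to 5.50). GPAM was 154-fold lower (log2 -7.07, interval -8.14 to -6.52), and CPS1, which encodes the entry enzyme of the urea cycle, 60.8-fold lower (-5.68, interval -6.94 to -5.08). AFP, the alpha-fetoprotein gene, was 7.24-fold lower. Among 2653 listed genes of at least 1 CPM, 1582 were at least 2-fold higher and 938 at least 2-fold lower, so 62.8% were higher.

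Of the 39 HIF targets 32 were listed for Hep3B and all 32 were higher (median 2.65, percentile 100). They included PPFIA4 (5.03), PFKFB4 (4.63, shared reads), EPO (2.35) and VEGFA, the vascular growth factor gene, at 1.37. All 14 listed glycolysis genes were higher (median 1.67, percentile 99.4), with 1 of the 14 turned lower under median-ratio scaling; ENO2 stood at 5.16 and PFKP went from 1 read to 68 (log2 4.49, counting interval 3.48 to 11.33). SLC2A3 had the highest log2 ratio with the prior count among genes of at least 5 CPM (9.14, interval 8.36 to 11.60), with shared reads. By plain CPM folds the ranking differed, with MDGA1 at 844 and SLC2A3 at 836. The oxygen-sensing prolyl hydroxylase genes EGLN3 (1.89) and EGLN1 (1.41) were the 2 listed HIF pathway regulators. All 6 listed mitophagy and autophagy genes were higher (median 2.12, percentile 99.4), with BNIP3 at 3.01, BNIP3L at 2.82 and OPTN at 2.04.

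NRF2 targets had 12 listed members, all higher (median 2.23, percentile 99.97), with 1 of the 12 turned under median-ratio scaling. The aldo-keto reductase genes AKR1C2 (6.09) and AKR1C1 (5.40), both with shared reads, led them, and AKR1B10 was at 3.81. All 14 listed integrated stress response genes were higher (median 1.84, percentile 99.9), including GDF15 (2.97), CHAC1 (2.62) and DDIT4 (2.36). The 4 listed heat shock genes were higher (median 3.08, percentile 99.6), among them CRYAB (4.50), HSPA1A (2.88, shared reads) and BAG3 (1.2). Early response genes had 6 members higher, KLF4 (2.61) and KLF2 (2.19) among them, and EGR1 lower at -2.46 (median 2.11, percentile 98.9). In the extracellular matrix and EMT list all 8 members were higher (median 2.11, percentile 98.8), with LOXL2 at 5.55, while 2 of the 8 turned under median-ratio scaling. ER chaperone genes had 4 lower, including SDF2L1 (-1.80) and PDIA4 (-1.11), and DNAJB9 higher at 1.23 (median -1.07, percentile 30.9).

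Few members of the fixed lists for DNA repair and cell division were listed for Hep3B, while 9 of 18 ferroptosis genes were. ADPRS (1.35), whose product removes ADP-ribose from serine, was the only listed gene of parthanatos and poly(ADP-ribose) turnover, and PARP1, PARG and MIF had no entry. LIG3 (-0.93, shared reads) was the only listed gene of alkylation and base excision repair, CDT1 (1.07, turned to lower under median-ratio scaling) the only S phase gene and PLK1 (-1.17) the only G2 and M phase gene, and no homologous recombination gene was listed. In the apoptosis list BAD (1.40) and BMF (1.14) were higher and the other listed member lower (median 1.14, percentile 60.3), and BMF turned to -0.03 under median-ratio scaling. In the necroptosis and pyroptosis list NINJ1 (1.24) and GSDME (1.04) were higher and PYCARD (-1.27) and MLKL (-1.17) lower, with GSDME at -0.12 under that scaling (median -0.06, percentile 25.8). Ferroptosis genes had 6 higher and 3 lower (median 1.15, percentile 68.5; -0.02 under median-ratio scaling), with ACSL4, which makes the lipids that are oxidised in ferroptosis, at -3.03. Histone genes had 1 higher and 1 lower, both lower under median-ratio scaling.

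Hepatocyte genes were lower in Hep3B as groups. All 17 listed hepatocyte secreted proteins were lower (median -2.07, percentile 0.015), among them F2, the prothrombin gene (-3.45), SERPINA3 (-2.28), FGG (-2.18) and ALB (-1.28). The hepatocyte metabolism list had 7 lower and 1 higher (median -4.24, percentile 0), with ADH4 going from 148 reads to 2 (-5.29, interval -9.35 to -4.41) and ARG1 at -4.26. Of 11 listed genes of fatty acid synthesis and storage 10 were lower (median -1.81, percentile 0.11), with FABP1 at -3.50 and PLIN5 at -2.30, and all 11 listed cholesterol synthesis genes were lower (median -1.40, percentile 1.38), with SQLE at -1.77 and HMGCS1 at -1.75. The 4 listed fatty acid oxidation genes were lower (median -1.47, percentile 4.86), PPARGC1A at -1.54 among them. Oncofetal markers had 8 lower and 1 higher (median -1.42, percentile 2.77), with DLK1 at -4.34, AFP at -2.85 and LIN28B at -2.38. NAD metabolism had TDO2 (-2.54) and NADK2 (-1.76) among 3 lower and NADSYN1 (1.43) higher (median -1.80, percentile 3.46). The 3 listed respiratory chain genes ATP5MC1 (-1.54), UQCRC2 (-1.2) and COX5A (-1.0) were lower (percentile 21.6).

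All 9 listed inflammatory chemokine and NF-kB genes were lower in Hep3B (median -2.77, percentile 0.01), among them the chemokine genes CCL20 (-4.09), CXCL2 (-3.65) and CXCL5 (-2.77), and LCN2, at 81 reads under normoxia and 0 under hypoxia, was at least 28.5-fold lower. A larger gene set for TNF signalling through NF-kB, given under other observations, went the other way in Hep3B, with 53 genes higher and 23 lower (median 1.49). The 3 listed interferon-stimulated genes IRF7 (1.92), IRF9 (1.14) and ISG15 (1.07) were higher, but IRF9 and ISG15 turned to -0.01 and -0.10 under median-ratio scaling. Markers of other cell types went both ways: LYZ (-7.27, shared reads), CD14 (-2.04), CD68 (-1.49), PECAM1 (29 reads to 1, -3.42, interval -10.29 to -2.34) and PDGFRB (-2.12) were lower, and COL1A1 (3 reads to 427, 6.36, interval 5.52 to 9.36) and LUM (1.76) higher. Outside the lists MDGA1 went from 1 read to 890 (8.16, interval 7.24 to 15.03), SLC2A2, the hepatocyte glucose transporter gene, from 577 reads to 1 (-7.64, interval -14.56 to -6.77), EHF from 590 reads to 2 (-7.27, interval -11.33 to -6.42), and SRARP was at least 105-fold lower. SULT1A4 (at least 292-fold higher), COMMD3-BMI1 (at least 124-fold higher) and the melanoma antigen genes MAGEA6 (-8.00) and MAGEA3 (-7.49) share reads with close copies or overlapping genes. With TMM 45.6% of the 2-fold genes were higher (837 higher, 1000 lower) and with median-ratio factors 35.8% (559 higher, 1001 lower), which shift each log2 ratio by -0.661 and -1.17. As in Huh7, these shares are not comparable between scalings.

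**Figure D2:**
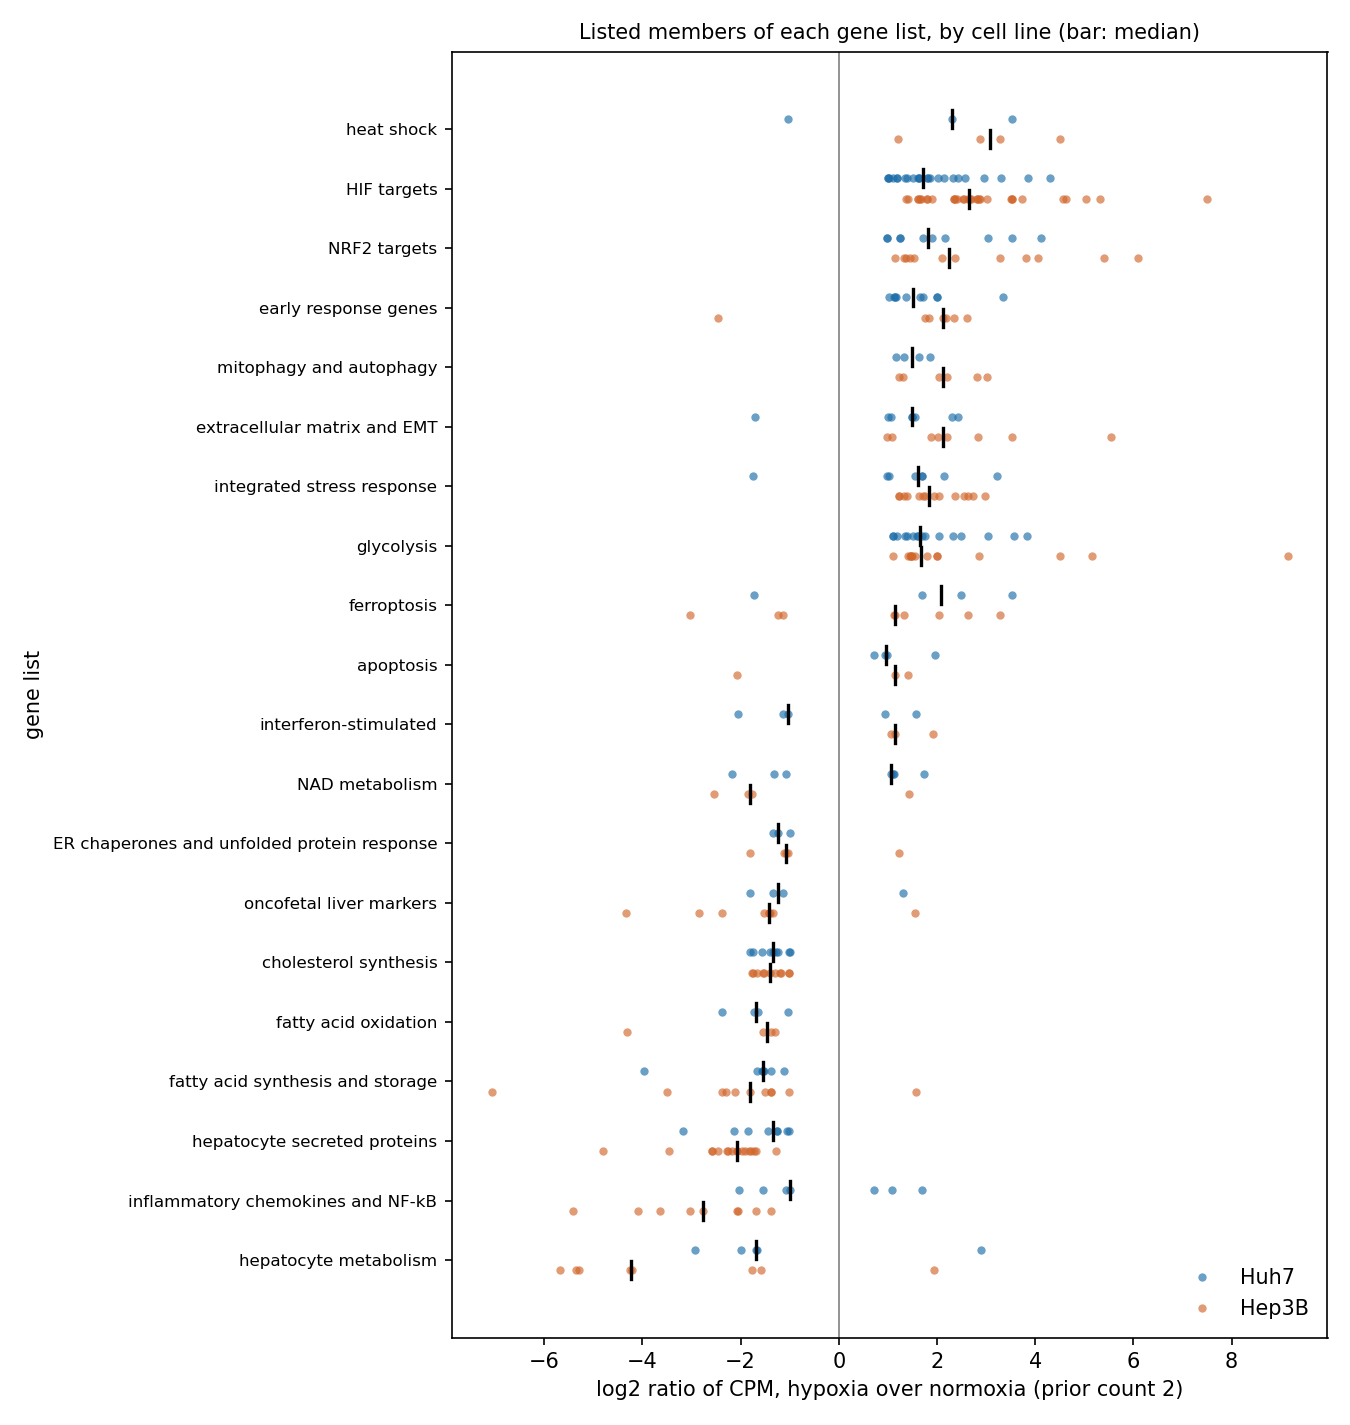
Log2 ratio of CPM, hypoxia over normoxia (horizontal axis), for each listed member (points) of gene lists with at least 3 listed members in both lines, in Huh7 (blue) and Hep3B (orange), with black bars at the medians. The bars for HIF targets stand at 1.71 and 2.65 and those for hepatocyte secreted proteins at -1.35 and -2.07, though under median-ratio scaling 2 of the 8 Huh7 members of the latter were higher.

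Across both lines, the response held the same direction for most genes that stood in both tables. Of 776 genes of at least 1 CPM in both, 711 differed at least 2-fold in both lines, 353 of them higher in both and 304 lower in both, so 657 (92.4%) went the same way, against 357 if the directions of the lines were independent. PPFIA4 (NCBI gene 8497, chromosome 1 from 203026491 to 203078736) had a mean log2 ratio of 4.66 ± 0.51 (SD, n = 2 lines), HMOX1 (NCBI gene 3162, chromosome 22 from 35381096 to 35394207) 3.40 ± 0.18 and GPAM (NCBI gene 57678, chromosome 10 from 112149865 to 112216306) -5.52 ± 2.19. The log2 ratios of the lines correlated across genes, which are not independent replicates, with Pearson's r of 0.764 (gene-resampled interval 0.723 to 0.803) and Spearman's rho of 0.735 (0.693 to 0.776). Genes with small ratios had been filtered out of both tables, so nearly all shared genes were bound to differ 2-fold. The correlations lack such genes and in part restate the shared direction.

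Shared higher genes were led by PPFIA4, NPPB (3.96 in Huh7 and 7.29 in Hep3B), ANGPTL4 (3.84 and 7.49), AKR1B10 (4.11 and 3.81), ENO2 (3.57 and 5.16), PFKFB4 and HMOX1. SLC2A3, P2RY11 (at least 10.9-fold and at least 97.1-fold), ZASP (3.73 and at least 14.6-fold) and LDLRAD2 (3.51 and 5.22) also ranked among the 12 highest, with shared reads in at least 1 line. Shared lower genes were led by GPAM, SPTLC3, a sphingolipid synthesis gene (-3.16 and -3.19), KIAA0754 (-3.44, 54 reads to 3, interval -6.43 to -2.49, and -2.65), SERPINA7, the thyroxine-binding globulin gene (-2.59 and -2.92), AGXT (-2.54 and -4.78), HLF (-2.49 and -3.26), RFX6 (-2.43 and -4.79) and the complement gene CFB (-2.40 and -3.87). HP, the haptoglobin gene (-3.18, and -4.79 on 2 reads under hypoxia, interval -8.86 to -3.90), SLCO1B3 (-2.80, and -5.06 on 1 read, interval -11.95 to -4.12) and BIVM-ERCC5 (at least 15-fold lower, and -2.69) share reads.

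**Figure D3:**
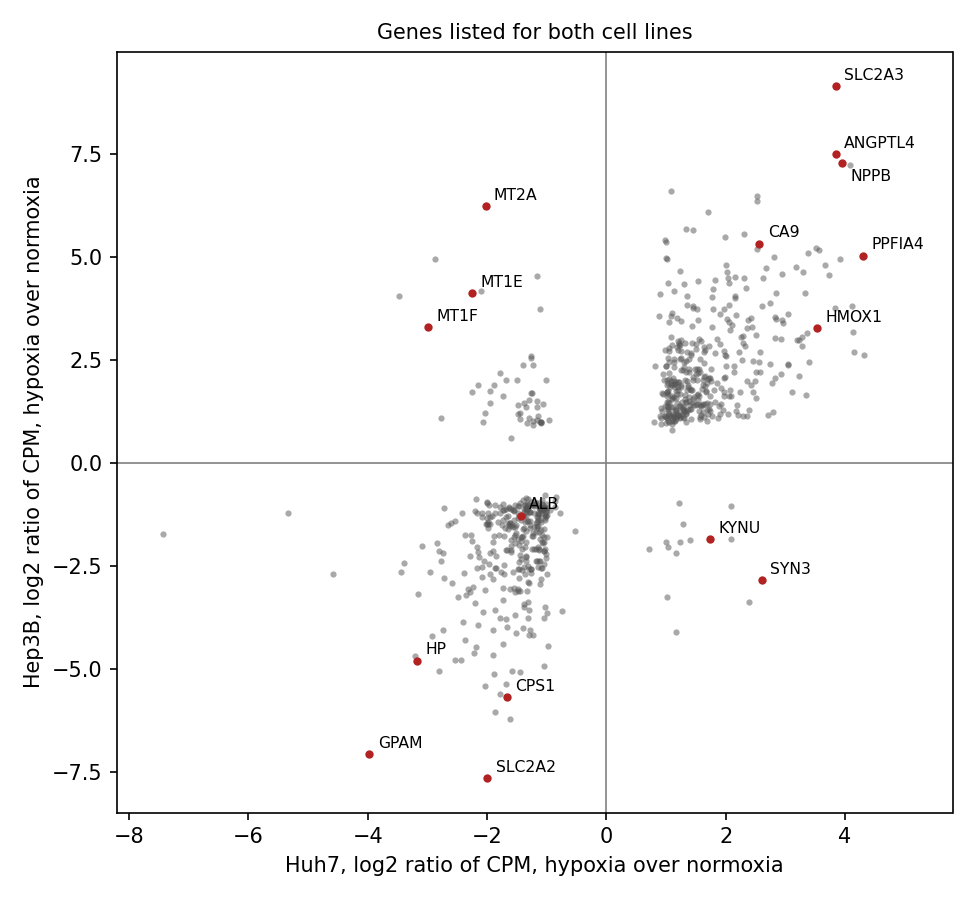
Log2 ratio of CPM, hypoxia over normoxia, in Huh7 (horizontal axis) and Hep3B (vertical axis) for each gene of at least 1 CPM in both tables (grey points), with some genes named in red. Of the 711 genes at least 2-fold different in both lines, 657 lie in the upper right or lower left and 54 in the other 2 quadrants, among them MT2A, which was lower in Huh7 and higher in Hep3B.

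With the lines as replicates, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment passed 0 of 784 genes at an adjusted p under 0.05, the smallest adjusted p being 0.0739; 460 genes had an unadjusted p under 0.05, while DESeq2 passed 488 (265 higher, 223 lower) and limma on log2(FPKM + 1) passed 464 of 714 (258 higher, 206 lower). The gene lists, fixed beforehand, gave a different count when the edgeR p-values were adjusted over the list alone. HIF targets had 24 members in both tables, all higher in both, of which 17 passed adjusted over the list alone and 0 over all genes tested (19 at an unadjusted p under 0.05, 23 with DESeq2, 17 with limma). For glycolysis 12 of 14 passed over the list alone (14 with DESeq2, 12 with limma over all genes), for the integrated stress response 5 of 7 (7 and 5), for NRF2 targets 4 of 7 (7 and 5), for early response genes 5 of 5 (4 and 5), for extracellular matrix and EMT 3 of 4 (3 and 4), and for mitophagy 3 of 3 (3 and 3), every one of these members being higher in both lines. For cholesterol synthesis 6 of 6 passed over the list alone (6 with DESeq2, 6 with limma over all genes), for fatty acid synthesis 6 of 7 (7 and 5), for fatty acid oxidation 2 of 3 (3 and 3), for hepatocyte secreted proteins 1 of 7 (6 and 5) and for hepatocyte metabolism 1 of 4 (3 and 2), every one of these members being lower in both.

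With edgeR smaller overlaps gave 4 of 4 oncofetal genes (1 higher, 3 lower; 3 with DESeq2 and 4 with limma over all genes), 3 of 3 ferroptosis genes (2 higher, ACSL4 lower; 3 and 3), 2 of 2 heat shock genes (2 and 2), 2 of 3 NAD metabolism genes (TDO2 and NADK2, lower; 1 and 2) and 1 of 2 apoptosis genes (BMF; 1 and 1) as passing when adjusted over the list alone, and 0 of 4 inflammatory genes (3 and 2), of which 3 were lower in both. Lists with 1 member in both tables need no adjustment over the list, and PDIA4 and ISG15 had an unadjusted p under 0.05 and passed with DESeq2 and limma over all genes, while LIG3 had an unadjusted p under 0.05 and passed with limma but not with DESeq2. Of the markers of other cell types found in both tables, COL1A1 passed with DESeq2 and limma but not with edgeR, and CD68 with none. Over all genes tested edgeR passed 0 members of every list. GDF15, of the integrated stress response list, had a mean log2 ratio of 3.10 ± 0.18 (SD, n = 2 lines), and ALB, of the hepatocyte secreted proteins, -1.36 ± 0.11. Because the genes tested had been selected by the authors for differing in these same libraries, neither the shared directions nor the counts over a list are independent evidence, and no p-value measures spread between separate cultures of a line.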

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

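For the metallothionein pattern the tests on transcript length, on RNA from the other line and on exchanged labels were chosen only after the result was seen. The difference between the lines was not tested for any value given here, because each line had 1 library per condition.

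In 54 genes of the 711 that differed at least 2-fold in both lines, the lines went opposite ways. SYN3 had a log2 ratio of 2.60 in Huh7 and -2.84 in Hep3B, with shared reads, and KYNU, a kynurenine pathway gene, 1.73 and -1.84, also with shared reads. ACSL5, an acyl-CoA synthetase gene, had 1.40 and -1.87, the macrophage marker CD68 1.28 and -1.49, and UNC93A 1.17 and -2.19. IGSF9 went the other way, at -2.10 in Huh7 and 4.18 in Hep3B. The median of NAD metabolism genes was 1.07 in Huh7 and -1.80 in Hep3B, over 7 and 4 listed members. Of the 3 found in both tables TDO2 and NADK2 were lower in both lines, and the Huh7 median ran from -1.33 to 1.13 over resampled members. The median of interferon-stimulated genes was -1.03 and 1.14, over 5 and 3 listed members, of which only ISG15, higher in both lines, was shared, and its sign turned in either line under median-ratio scaling (0.07 and -0.01).

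Metallothioneins, small metal-binding proteins encoded in a cluster on chromosome 16, were lower under hypoxia in Huh7 and higher in Hep3B. MT1F, MT1G, MT1E and MT2A kept these directions under every scaling tried. The other members were not put through the other scalings, among them MT1X at -1.16 in Huh7, where median-ratio factors add 1.13. MT1F stood at -2.99 in Huh7 and was at least 5.69-fold higher in Hep3B, MT1G at -2.88 and at least 19.3-fold, MT1E at -2.25 (shared reads) and 4.13 (3 reads to 89, interval 3.22 to 7.12) and MT2A at -2.03 and 6.24. Reads shared between paralogs would leave the sum of the family in place. Over listed members it was 59.6-fold higher in Hep3B (3.53 to 211 CPM, 5 members) and 4.70-fold lower in Huh7 (4987 to 1061 CPM, 8 members). Listed members all went the same way within a line, so these sums had to move. Reads exchanged with unlisted copies are therefore not ruled out. The Huh7 length trend ran the other way, with 76.3% of the shortest genes (the lowest of 5 equal groups) higher. Huh7 RNA in the Hep3B hypoxia library would keep the Huh7 proportions. Yet the ratio of MT2A to MT1G was 42.9 there and 4.41 in Huh7 normoxia, 9.72 times apart. MT1X departed too (485 reads to 61 of MT1G, against 2884 to 8858), but MT1E did so less (89 to 61, against 16470 to 8858). Such RNA is thus not excluded for MT1E and MT1G. Exchanged labels in a line would turn its HIF targets, of which 56 of 56 listed entries were higher under hypoxia. A difference in the response of the lines may remain as a hypothesis, found and examined on the same libraries. Reads shared with unlisted copies and a difference between single cultures, such as metal in the medium, were not tested and remain beside it.

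In Huh7 a gene lower under hypoxia had the longer transcript than a gene higher with a probability of 0.811 (interval over resampled genes 0.792 to 0.829), against 0.518 (0.497 to 0.540) in Hep3B. Among genes without an entry for Hep3B it was 0.848, so short hypoxia genes shared by the lines do not account for it. Within groups of like GC content it was 0.751, so GC content is not the whole of it. Within groups of like length a lower gene had the higher GC content with a probability of only 0.199 in Huh7 and 0.348 in Hep3B. Genes higher under hypoxia thus mostly had the higher GC content in both lines. In Huh7 this relation was at least as strong as that of length, and no list was matched on GC content. Loss of long RNA in the Huh7 hypoxia library stays open, since within groups of like genomic span the length probability was 0.694 (0.665 to 0.723). Less transcription through long genes stays open as well, since within groups of like transcript length the lower gene had the longer span with a probability of 0.640 (0.608 to 0.667). Either may contribute, and hypoxia itself and the single Huh7 hypoxia library are the same sample here.

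Genes with fractional reads stood out among the most extreme ratios. In Huh7 35.8% of the 5% of genes with the largest ratios had fractional reads against 18.3% of the rest (1.95 times), and in Hep3B 30.4% against 17.9% (1.69 times), which is consistent with reads moving between overlapping or near-identical genes. Low read numbers could also do this: with at least 100 reads the excess was 1.33 times in Huh7 (interval 0.834 to 1.87) and 1.62 in Hep3B (1.11 to 2.19), so in Hep3B an excess is left with more reads, while in Huh7 the interval is too wide to separate the explanations. No biological explanation was tested for this pattern.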

How the results depend on the processing

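Chosen after the data were seen were totals of the listed reads, leaving out genes with fractional reads, a split of genes at the median transcript length, length-matched lists and TPM for lists. The 0 genes passed by edgeR stayed 0 under both scalings, both count filters, without the line block and without fractional genes. Leaving out a line or library leaves no residual degree of freedom, so only the other line's value remains; with 2 lines either value always lies within 1 SD of their mean, so the 136 such values of named genes say nothing of stability. Of 145 counts and correlations 102 moved by less than their limits and 43 moved; of 192 list medians 121 stayed, 60 moved and 11 reversed; of 1648 values of named genes within a line 1009 stayed, 627 moved and 12 reversed. Of 599 values of named genes over both lines 114 newly passed, all with DESeq2 (63 of 78) or limma (51 of 74). Unless the setting itself lowers the number of genes, the cause was not tested. Depth limits genes with few reads, whose intervals span several log2 units, and no replicate shows how far libraries of a condition differ.

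Over both lines DESeq2 passed 488 genes and limma 464 with a pseudocount of 1, 351 with 0.1, 467 with 0.5, 434 unfiltered and 392 with an FPKM of at least 5.

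With TMM Huh7 had 944 genes at least 2-fold different, 205 of them lower, Hep3B had 837 higher, and across lines 333 went the same way and 25 opposite ways. With median-ratio factors Huh7 had 881 (142 lower), Hep3B 1560 (559 higher), and 231 went the same and 20 opposite ways. At 10 CPM, with fewer genes, Huh7 had 418 higher, Hep3B 1645 in all (992 higher), and 405 went the same and 23 opposite ways. With FPKM Huh7 had 1143 (646 lower), Hep3B 1039 higher, and 422 and 17 went the same and opposite ways. With TPM Huh7 had 349 higher, and 437 and 22 went the same and opposite ways. At 4-fold, a stricter limit, Huh7 had 344 (181 higher, 163 lower), Hep3B 956 (605 higher, 351 lower), and 126 and 8 went the same and opposite ways. Among genes with shorter transcripts 343 and 19 did, and among those with longer ones 314 and 35, with a Spearman's rho of 0.678.

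Medians that reversed under median-ratio scaling, which shifts every gene alike, were those of alkylation and base excision repair (0.0370), inflammatory chemokines (0.11) and interferon-stimulated genes (0.0684) in Huh7, and of apoptosis (-0.0270), ferroptosis (-0.0189) and interferon-stimulated genes (-0.00728) in Hep3B. At 10 CPM inflammatory chemokines (0.71) and interferon-stimulated genes (0.95) reversed in Huh7. With TPM interferon-stimulated genes in Huh7 (0.0202), and necroptosis and pyroptosis (0.10) and endothelial and stellate markers (0.77) in Hep3B, reversed. Single genes that reversed under median-ratio scaling included NDUFV1, Huh7 (0.0136), NADK2 (0.0528), LIG3, Huh7 (0.26, and 0.0451 with TMM), PALB2 (0.00321), RAD51AP1 (0.0920) and CXCL2 (0.11) in Huh7, and BMF (-0.0270), GSDME (-0.12), ISG15 (-0.10) and IRF9 (-0.00728) in Hep3B.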

Other observations

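Hallmark gene sets, as the deposited tables annotate them, were examined after the data were seen, and hold only genes that had passed the authors' thresholds. In both lines the epithelial-mesenchymal transition set was higher, with 31 genes higher and 11 lower in Huh7 (median log2 ratio 1.26) and 48 higher and 13 lower in Hep3B (1.93), and the set for TNF signalling through NF-kB had 41 higher and 13 lower (1.25) and 53 higher and 23 lower (1.49). The inflammatory chemokine and NF-kB list fixed beforehand did not share this rise. It had 3 members higher and 4 lower in Huh7, and 0 higher and 9 lower in Hep3B (median -2.77). The hypoxia set had 60 higher and 5 lower in Huh7 (1.51) and 78 higher and 13 lower in Hep3B (1.93). Liver-linked sets were lower in Hep3B: coagulation had 19 genes higher and 34 lower (median -1.65, percentile 0 of random lists), complement 20 higher and 27 lower (-1.5, percentile 0) and bile acid metabolism 7 higher and 25 lower (-1.41, percentile 0.01). In Huh7 the same sets had medians of -1.22, -1.20 and -1.34, at percentiles 6.56, 11.6 and 1.66, and with TMM of -0.31, -0.29 and -0.43.

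In Huh7 E2F targets had 37 genes lower and 3 higher (median -1.19, percentile 3.66). The G2M checkpoint set had 31 lower and 3 higher (-1.21, percentile 4.42) and the mitotic spindle set 28 lower and 6 higher (-1.22, percentile 6.89). Among random lists matched on length and more coarsely on expression these sets stood at 13.1, 11 and 30.1. Their medians under TMM were -0.28, -0.30 and -0.31. In Hep3B E2F targets had 5 higher and 4 lower, the G2M set 13 higher and 9 lower and the mitotic spindle set 16 higher and 6 lower. The unfolded protein response set had 5 higher and 9 lower in Huh7 (median -1.08) and 12 higher and 2 lower in Hep3B (1.66), a difference that was not tested. In Huh7 the set lay amid the random lists, at percentile 51.9 (78.8 with length matched), with a median of -0.18 under TMM. In Hep3B it stood at percentile 99.2, with a median of 0.998 under TMM. The ER chaperone and unfolded protein response list fixed beforehand did not share the Hep3B rise. It had 1 member higher and 4 lower there (median -1.07, percentile 30.9).

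Of the metallothionein cluster 8 genes were listed for Huh7 and all were lower, from MT1X at -1.16 to MT1H at -3.49, and 5 were listed for Hep3B and all were higher, MT1X at 4.53. The FPKM total of a library, recovered from the deposited FPKM and TPM, was 17.8% higher under hypoxia than under normoxia in Huh7 and 1.87% higher in Hep3B. If 2-fold genes of each line were independent lists, 54.4 genes would be higher in both and 62.6 lower in both among 20056 protein-coding genes, or 271 and 312 among the 4029 genes in either table, against 353 and 304 observed; the number of genes the authors could have tested is not known here.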
